A study of Homo sapiens with 10 samples.

How the data were processed

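RNA sequencing was analysed from 10 libraries of human lung cells: fibroblasts that the labels call FLF, and pericytes, the mural cells of small vessels. Each cell type had control libraries and libraries with knockdown (KD) of TBX4, a T-box transcription factor of the lung mesenchyme. There were 2 control and 2 KD libraries of FLF and 3 control and 3 KD libraries of pericytes, with groups and replicate numbers taken from the sample titles. The abbreviation FLF, the knockdown method, the vectors and the donors are not given in the sources used here. The series design also names ChIP-seq, which was not analysed here.

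RNA was isolated with a commercial extraction kit and libraries were made by standard Illumina methods, per the labels' protocols. Partek and HISAT2 are named without role or version, and genome build hg38 is named, per the submitters' processing notes. The annotation, read filters and strand setting of the counting are not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. The deposited table holds CPM (read counts relative to the library total) for 24173 genes, scaled by the authors to the same total in every library, with 0.001 added to every value. All 10 columns of values were matched to samples by name.

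Depth was estimated from the values. After the offset of 0.001 was taken off, low values lay on multiples of one step per library, and that step was taken as the value of 1 read. Of values up to 20 such steps, 86.1 to 88.2% lay within 0.1 of a whole number. This left too many values between the steps for the table to be treated as whole reads. The steps correspond to 37.0 to 54.7 M reads per library. A count of 0 allows up to 3 reads, or 0.0548 to 0.0810 CPM, and this limit covers counting error only. Genes near that level carry little information on change.

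The planned analysis had 1 branch for counts and 1 for normalized values. The table held CPM, so the branch for normalized values was used. Values were taken as log2(CPM + 1), and fold changes on that scale understate the change of genes with low CPM. Genes with at least 1 CPM in as many libraries as the smaller group were tested (2 for FLF, for the control comparison and for the joint model, 3 for pericytes). Y-linked genes, XIST and TSIX were left out, 11 in all. Differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance moderation, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. Every adjusted p of a gene below comes from limma. Each cell type was fitted alone for the KD effect.

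The pericyte libraries carried 2 library-code series in their descriptions. The larger series held controls 2 and 3 and KD 1 and 2, and the smaller held control 1 and KD 3. The code was a term of the pericyte model. Pericyte changes are followed below by the change within the larger series and the change in the single pair of the smaller series. The difference of the KD effect between cell types (pericytes minus FLF) was an interaction term in 1 model of all 10 libraries. Control pericytes were compared with control FLF in the 5 control libraries, where cell type and library numbering cannot be told apart. Overlap of calls was tested with the two-sided Fisher exact test over genes tested in both cell types. No library was shared between those comparisons.

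Gene lists for 42 pathways, complexes and cell types were fixed before the data were examined, as were the tests and the rule for naming genes. Lists with at least 5 tested members were tested with camera, in limma, with a preset correlation of 0.01 and again with a correlation estimated from the libraries, and adjusted over the lists. Markers of pericytes, fibroblasts, contractile smooth muscle, endothelium, epithelium, immune cells and mesothelium were among them. The rule named TBX4, then per KD comparison the 8 genes that rose most and the 8 that fell most. Those had to pass the threshold, lie above the median of expression and have every KD library beyond every control, and clone-style names were left out. It further named up to 4 called members per list (2 by unadjusted p where none was called), 8 genes called the same way in both cell types, 4 called in opposite ways, 4 per direction for the interaction and 3 per direction between controls. Of the genes the rule named, 1 called in opposite ways is not reported here.

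The search of 3' UTRs used the longest 3' UTR of at least 50 bases per gene in the GENCODE annotation, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. For each 7-base word in at least 100 genes, a z compared log2 fold changes of genes with and without the word. UTR length, GC content and expression were regressed out, changes were limited to 1.5, and TBX4 was left out. The z values were compared with 100 shufflings of genes. The expression term and the limit on changes were not part of the written plan of the search, and the 6-base core words were chosen after the search was seen. Plots were drawn with matplotlib 3.10.9.

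The pipeline was tested on simulated data made from the libraries' own means and spread, with 50 genes changed at each fold. In the FLF design (13708 genes), 16% of changes of 1.23-fold, 76% of 1.5-fold, 92% of 2-fold and 100% of 4-fold were recovered, and 7.79% of calls were false. In the pericyte design (14315 genes), the shares were 0%, 42%, 76% and 90%, and 2.80% of calls were false. Far fewer genes were changed than limma called in the data, which makes the adjusted threshold stricter. In pericytes the simulated spread included the difference between the code series, and a code effect of set size was added. The shares are therefore not the recovery in the real libraries. Libraries of a group differed by more than counting noise in every pair (chi-square per gene 2.35 to 70.8). This does not show that they are separate cultures or preparations. Each was counted as 1 replicate by its label, and whether that spread is technical was not tested. Pericyte pairs within the larger code series stood at 2.35 and 3.04, and pairs across the series at 19.9 to 70.8. Alternatives covered the pseudocount, the filter, scaling, the model, the library code, a replicate block and leaving out each library.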

Results

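Transcript levels were measured by RNA sequencing in 10 libraries of human lung fibroblasts (FLF) and lung pericytes, with and without knockdown (KD) of TBX4. There were 2 libraries in each FLF group and 3 in each pericyte group, at an estimated depth of 37.0 to 54.7 M reads per library. Levels are given as mean ± SD in CPM over the libraries of a group, and changes as log2 fold changes on the log2(CPM + 1) scale. No label states that replicates were separate cultures or donors, so p-values measure the spread between these libraries, which may be technical. The knockdown libraries of FLF separated from controls on a first principal component with 83.6% of the variance. In pericytes that component held 53.2%. A second one, with 31.6%, set apart the 2 libraries of the smaller code series, control 1 (score 31.4) and less so KD 3 (4.58). The other pericyte libraries lay at -7.94 to -10.5.

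TBX4 (ENSG00000121075) lies on the plus strand of chromosome 17 at positions 61452404 to 61485110 of hg38. Its transcript fell in both cell types. In FLF it went from 66.3 ± 3.87 to 30.9 ± 1.86 CPM, a log2 change of -1.08 (SE 0.0575, adjusted p = 4.22e-11), leaving 46.6% of the control level. In pericytes it went from 9.22 ± 2.56 to 1.82 ± 0.168 CPM, a change of -1.83 (SE 0.161, adjusted p = 0.00035), leaving 19.7%. The pericyte change was -2.06 within the larger code series and -1.35 in the other pair. Every KD library lay below every control library of its cell type, and the exact permutation p-values of 0.333 in FLF and 0.1 in pericytes were the smallest these group sizes allow.

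**Figure D1:**
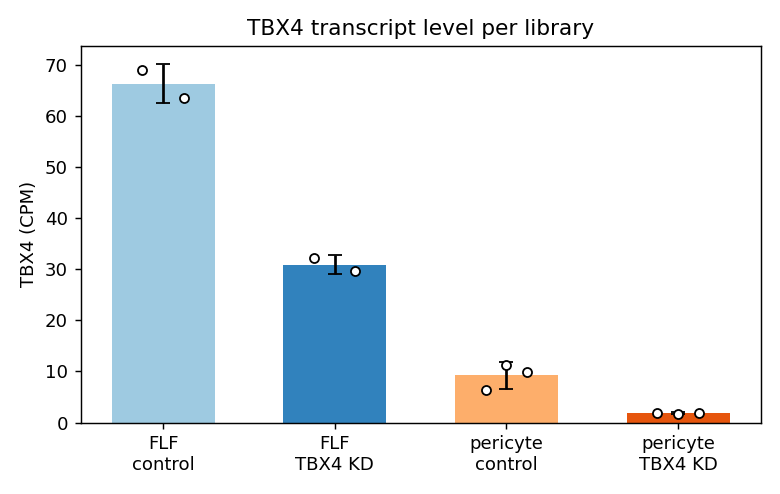
TBX4 transcript level in CPM in each group. Bars are means, whiskers are SD over 2 FLF or 3 pericyte libraries per group, and points are single libraries; mean levels were 66.3 and 30.9 CPM in FLF control and KD and 9.22 and 1.82 CPM in pericyte control and KD.

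The FLF comparison asked which transcripts changed in fibroblasts when TBX4 was lowered. The list of ATF4 stress response genes rose, and the lists of mitosis, DNA replication, interferon response and HLA class I presentation fell. These lists passed with the preset correlation and not otherwise (adjusted p = 0.45 to 0.57 with an estimated correlation). HMOX1, the inducible heme oxygenase, rose from 61.7 ± 2.84 to 235 ± 2.28 CPM (log2 change 1.91, adjusted p = 2.89e-16). CPA4, a carboxypeptidase, fell from 80.5 ± 4.42 to 20.4 ± 0.535 CPM (-1.93, adjusted p = 7.22e-15). Of 13748 genes tested, limma called 6145, with 2679 higher and 3466 lower. Of these, 56 were higher and 57 lower by at least 2-fold. With quantile normalization 3090 were higher and 3044 lower, so the balance of directions in FLF depends on scaling.

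Among the strongest rises, ASNS, which makes asparagine, went from 34.1 ± 2.21 to 104 ± 5.20 CPM (log2 change 1.58). PSAT1 of serine synthesis went from 61.0 ± 2.15 to 173 ± 10.4 CPM (1.49). CHAC1, a glutathione-degrading enzyme, rose by 1.45, the pseudokinase gene TRIB3 by 1.35 and ALDH1L2, a mitochondrial folate enzyme, by 1.32. POSTN, which encodes the matrix protein periostin, rose from 15.5 ± 1.05 to 46.4 ± 2.76 CPM (1.52), and MET, the receptor for hepatocyte growth factor, from 53.5 ± 2.27 to 123 ± 1.81 CPM (1.18). Among the strongest falls, IRAK1, a kinase of interleukin and Toll-like receptor signalling, went from 292 ± 5.54 to 132 ± 3.59 CPM (-1.14). SLC2A4RG fell from 142 ± 5.86 to 57.7 ± 2.46 CPM (-1.28), and the cell cycle transcription factor MYBL2 from 68.3 ± 1.55 to 29.6 ± 1.32 CPM (-1.18). TRAK2, a mitochondrial transport adaptor, changed by -1.15, TNFAIP2 by -1.11 and the RNA-binding protein gene IGF2BP3 by -1.10. Adjusted p-values of these genes were at most 1.43e-08 in limma. All 7 of these falls, TBX4 aside, held the word TCAGGT in the 3' UTR, against 3 of the 8 rises (TRIB3, ALDH1L2 and MET) and 34.8% of all genes searched. The word was picked in these same data for marking falls, so the count is no separate support for it.

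Gene lists that rose in FLF were 4 of 40 tested. Of 37 targets of ATF4 and the integrated stress response, 31 rose and 2 fell (31 and 2 when adjusted over the list alone), with a median log2 change of 0.58. The list passed with the preset correlation (adjusted p = 3.47e-18) and not otherwise (adjusted p = 0.45 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme on that list, rose from 85.6 ± 1.98 to 188 ± 10.3 CPM (1.13). Of 24 NRF2 antioxidant genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 0.45 with an estimated correlation), at a median of 0.22. Besides HMOX1 these included GCLM of glutathione synthesis (0.65) and SRXN1 (0.34). Of 36 fibrillar matrix genes, 20 rose and 8 fell (22 and 10 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation), at a median of 0.20. SPARC rose from 1353 ± 33.1 to 2371 ± 18.4 CPM (0.81) and COL11A1 by 0.74, while FBLN1, a fibulin, fell from 250 ± 10.7 to 167 ± 1.45 CPM (-0.59).

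Of 13 mitochondrially encoded transcripts, 4 rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation), at a median of 0.58. MT-ND3 rose from 117 ± 0.692 to 175 ± 6.48 CPM (0.57). MT-ND4 went from 1232 ± 14.3 to 2039 ± 311 CPM (0.72, adjusted p = 0.0411), and its call was lost without control 1 (adjusted p = 0.286) or control 2 (adjusted p = 0.28). The calls of MT-CO3 and MT-ND5 were lost as well without control 1 (adjusted p = 0.301 and 0.278) or control 2 (adjusted p = 0.296 and 0.246), which leaves MT-ND3. The mitochondrial share of CPM was 1.23% and 1.28% in controls against 1.98% and 1.60% in KD 1 and 2. In the same libraries, 68 heart muscle genes, listed after their rise was seen, summed to 233 and 224 CPM in controls against 582 and 353 CPM in KD 1 and 2. Of the 37 tested, 25 rose and 1 fell. MYH7, the cardiac beta-myosin heavy chain, was listed at the offset in both controls and at 65.8 and 29.01 CPM in KD 1 and 2. LDB3, a Z-disc gene that is also on the contractile smooth muscle list, went from 0.249 ± 0.0403 to 7.06 ± 3.76 CPM (2.61, adjusted p = 0.025), and its call was lost without control 1 (adjusted p = 0.186) or control 2 (adjusted p = 0.19).

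Gene lists that fell in FLF were 7. Of 45 genes of G2 and mitosis, 42 fell and 0 rose (42 and 0 adjusted over the list alone), at a median of -0.37 (adjusted p = 8.12e-17 in camera, and adjusted p = 0.45 with an estimated correlation). The chromokinesin KIF4A fell from 85.9 ± 4.23 to 50.3 ± 0.125 CPM (-0.76), NUSAP1 by 0.55 and UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, by 0.52 on the log2 scale. Of 41 genes of DNA replication, 30 fell and 1 rose (32 and 1 adjusted over the list alone; adjusted p = 0.53 with an estimated correlation), at a median of -0.22. RRM2, a ribonucleotide reductase subunit, fell from 312 ± 10.7 to 195 ± 2.40 CPM (-0.68), and MCM5 of the replicative helicase from 164 ± 1.61 to 110.1 ± 1.10 CPM (-0.57). Of 44 interferon response genes, 26 fell and 0 rose (27 and 0 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation), at a median of -0.32. ISG15 fell from 96.7 ± 7.97 to 59.5 ± 0.668 CPM (-0.69) and EPSTI1 from 6.18 ± 0.386 to 2.30 ± 0.526 CPM (-1.13).

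Of 13 genes of HLA class I presentation, 11 fell and 0 rose (11 and 0 adjusted over the list alone; adjusted p = 0.45 with an estimated correlation), at a median of -0.38. HLA-B, whose reads can be shared with other HLA genes, went from 85.5 ± 1.81 to 52.5 ± 1.40 CPM (-0.69), and the immunoproteasome subunit gene PSMB9 from 10.4 ± 0.975 to 6.53 ± 0.572 CPM (-0.60). Of 36 genes of hypoxia and glycolysis, 26 fell and 1 rose (26 and 2 adjusted over the list alone; adjusted p = 0.53 with an estimated correlation), at a median of -0.23. The collagen prolyl hydroxylase P4HA2 fell from 116 ± 2.71 to 65.3 ± 1.28 CPM (-0.82) and the glucose transporter SLC2A1 from 127 ± 1.61 to 73.7 ± 0.189 CPM (-0.77). Of 59 nuclear genes of oxidative phosphorylation, 32 fell and 1 rose (33 and 1 adjusted over the list alone; adjusted p = 0.64 with an estimated correlation), at a median of -0.14, with NDUFA2 at -0.60. Of 29 p53 targets, 15 fell and 4 rose (15 and 5 adjusted over the list alone; adjusted p = 0.53 with an estimated correlation), at a median of -0.17. ZMAT3 fell by 0.98 and RRM2B by 0.74 on the log2 scale, while SESN2, which ATF4 also induces, rose by 0.96. The p53 list was no longer called without genes that hold TCAGGT in the 3' UTR (median -0.08, adjusted p = 0.199). In that setting 13 FLF lists were called, against 11 with all genes, and only the p53 list lost its call. TCAGGT was picked in these data for marking falls, so leaving out its genes takes fallen members out of a list that holds them. The loss therefore does not tie the fall of the p53 list to the word. Of the members that fell, 6 of 42 on the mitosis list, 7 of 26 on the interferon list and 9 of 26 on the hypoxia list held that word.

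Markers of cell types were not called as lists in FLF. Of 20 fibroblast markers, 6 rose and 11 fell (6 and 11 adjusted over the list alone; median -0.24, adjusted p = 0.845). INMT, one of them, went from 3.16 ± 0.264 to 0.856 ± 0.0628 CPM (-1.16). Pericyte markers (6 rose and 5 fell of 19, or 7 and 5 adjusted over the list alone; adjusted p = 0.558) and contractile smooth muscle genes (9 rose and 6 fell of 27, or 10 and 6 adjusted over the list alone; adjusted p = 0.394) moved both ways. Of 6 epithelial markers 4 fell (4 adjusted over the list alone; adjusted p = 0.138), and of 5 endothelial markers 2 fell (1 adjusted over the list alone; adjusted p = 0.657). Immune and mesothelial markers had under 5 tested members.

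**Figure D2:**
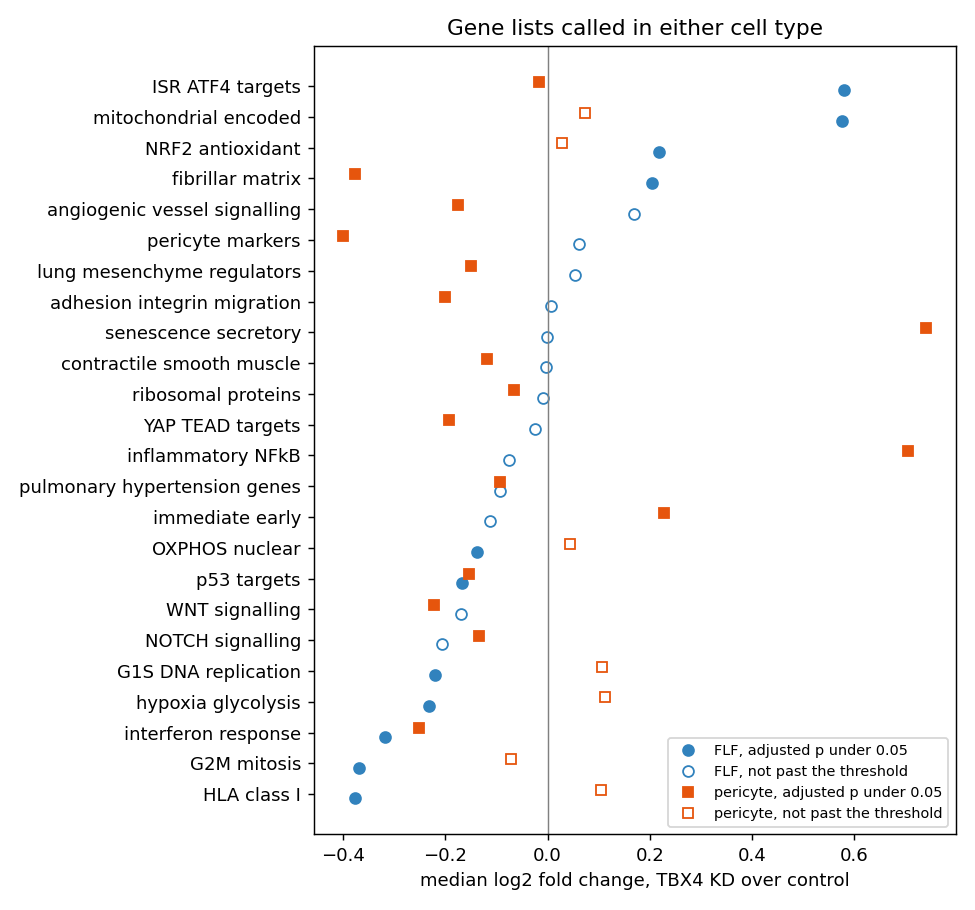
Median log2 fold change of TBX4 KD over control for each gene list called in FLF (circles) or pericytes (squares), on the horizontal axis. Filled symbols passed an adjusted p of 0.05 in camera with the preset correlation and open symbols did not; no list passed with an estimated correlation.

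The pericyte comparison asked the same question in pericytes. The list of inflammatory NF-kB genes rose, and the lists of pericyte markers, fibrillar matrix and interferon response fell. These lists passed with the preset correlation and not otherwise (adjusted p = 0.2, 0.2, 0.473 and 0.2 with an estimated correlation), and the matrix call was lost without control 1 (adjusted p = 0.0755) or KD 3 (adjusted p = 0.0743). IL1B, an inflammatory cytokine, went from 117 ± 105 to 747 ± 17.8 CPM (3.01, adjusted p = 0.0168; 3.72 in the larger series and 1.61 in the other pair). RGS4, a regulator of G-protein signalling, went from 134 ± 33.2 to 20.2 ± 0.312 CPM (-2.64, adjusted p = 0.000134; -2.88 and -2.17). Of 14340 genes tested, limma called 4732, with 2614 higher and 2118 lower, of which 88 were higher and 133 lower by at least 2-fold. Scaled by median of ratios, 1972 were higher and 2381 lower, so the balance of directions depends on scaling. The count was 7670 without control 1 and 7663 without KD 3, since each removal leaves the larger series alone to measure the change. Pericyte calls lost both without control 1 and without KD 3 therefore met nearly the same check each time. It was 2538 and 2468 without control 2 and 3, and 2453 and 2342 without KD 1 and 2. Without the code term it was 1825, with 843 higher and 982 lower.

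Among the strongest rises, CCL20, a chemokine, went from 54.5 ± 16.1 to 250.4 ± 17.2 CPM (2.22; 2.39 in the larger series and 1.87 in the other pair). CSF3, which encodes a granulocyte growth factor, went from 95.5 ± 13.8 to 402 ± 8.68 CPM (2.07, by series 2.17 and 1.87), and SAA2, an acute-phase protein gene, from 91.0 ± 2.95 to 314 ± 4.81 CPM (1.78, by series 1.75 and 1.84). IL1A went from 14.8 ± 10.05 to 63.5 ± 3.54 CPM (2.20, by series 2.64 and 1.32). MMP3, a stromelysin, went from 65.1 ± 59.5 to 250.2 ± 5.27 CPM (2.29, by series 2.96 and 0.93), and MMP1, a collagenase, from 472 ± 361 to 1701 ± 67.7 CPM (2.10, by series 2.65 and 0.999). The list of matrix-remodelling proteases was not called (9 rose and 7 fell of 32, or 10 and 7 adjusted over the list alone, adjusted p = 0.826). HEPHL1, a copper-dependent oxidase gene, went from 13.3 ± 13.2 to 80.7 ± 1.74 CPM (2.90, by series 3.62 and 1.45). Control 1 held more of IL1B, MMP3, MMP1 and HEPHL1 than the other controls (237.8 CPM of IL1B against 57.0 and 56.3). Without it the larger series alone measured the change, so the changes were those of that series (3.72, 2.96, 2.65 and 3.62). With control 1 kept, the calls of MMP3 and MMP1 were lost without control 2 (adjusted p = 0.102 and 0.0703) or control 3 (0.076 and 0.0536), KD 1 (0.105 and 0.0698) or KD 2 (0.0827 and 0.0543). HEPHL1 was lost the same way (0.0781, 0.0527, 0.063 and 0.0585), and IL1B without control 2 (0.0669), KD 1 (0.0702) or KD 2 (0.0523).

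Among the strongest falls, DDAH1, which degrades methylarginine inhibitors of nitric oxide synthase, went from 138 ± 13.1 to 36.1 ± 3.55 CPM (-1.90; -1.90 in the larger series and -1.89 in the other pair). CAPNS1, the small calpain subunit, went from 307 ± 5.04 to 82.5 ± 1.43 CPM (-1.88, by series -1.86 and -1.93), and CADM3, a cell adhesion molecule, from 102.5 ± 38.8 to 21.8 ± 0.460 CPM (-2.12, by series -1.84 and -2.68). ITGBL1 changed by -1.77 (-1.46 and -2.40), ADAMTSL1 by -1.54 (-1.64 and -1.32) and PRUNE2 by -1.46 (-1.37 and -1.66). SFRP1, a secreted WNT antagonist, went from 266 ± 158 to 54.7 ± 0.923 CPM (-1.99, adjusted p = 0.0461; -2.69 and -0.59). The SFRP1 call was lost without control 2 (adjusted p = 0.139), control 3 (0.109), KD 1 (0.143) or KD 2 (0.116). Without control 1 the change was that of the larger series, -2.69. Of these 8 falls, 6 held the word CCAGTA in the 3' UTR, all but CADM3 and CAPNS1, against 1 of the 8 rises (IL1A) and 28.0% of all genes searched. This word too was picked in the same data for marking falls.

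Gene lists that rose in pericytes were 3 of 41 tested. Of 33 inflammatory NF-kB genes, 21 rose and 2 fell (23 and 2 adjusted over the list alone), at a median of 0.70 (0.79 in the larger series and 1.06 in the other pair; adjusted p = 2.06e-08 in camera, and adjusted p = 0.2 with an estimated correlation). IL1B, CCL20, IL1A and CSF3 had its largest changes. Of 24 genes of the senescence-associated secretory program, 14 rose and 3 fell (14 and 4 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), at a median of 0.74 (0.79 and 0.97); it shares IL1B, CCL20 and IL1A with the inflammatory list. Of 25 immediate early genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), at a median of 0.23 (0.33 and 0.14). IER3 rose from 181 ± 37.0 to 397 ± 18.2 CPM (1.15, by series 1.27 and 0.90) and FOSB from 3.56 ± 0.757 to 6.81 ± 0.331 CPM (0.79, by series 0.93 and 0.51).

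Of the 14 lists that fell in pericytes, several mark mural cells and their matrix. Of 17 pericyte markers, 9 fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), at a median of -0.40 (-0.43 in the larger series and -0.45 in the other pair). CSPG4, the NG2 proteoglycan gene, fell from 204 ± 18.2 to 96.8 ± 2.61 CPM (-1.06, by series -0.97 and -1.24), and PDGFRB, a platelet-derived growth factor receptor, from 44.7 ± 2.62 to 26.2 ± 0.239 CPM (-0.75, by series -0.71 and -0.82). Of 33 fibrillar matrix genes, 13 fell and 3 rose (15 and 5 adjusted over the list alone; adjusted p = 0.473 with an estimated correlation), at a median of -0.38 (-0.12 and -0.58). COL1A2 fell from 1102 ± 368 to 440.2 ± 5.96 CPM (-1.27, by series -1.02 and -1.77), COL3A1 from 202 ± 61.6 to 82.2 ± 1.64 CPM (-1.24, by series -1.01 and -1.72) and LOX, a collagen cross-linking enzyme, from 482 ± 190 to 196 ± 4.90 CPM (-1.23, by series -0.91 and -1.88). Of 25 contractile smooth muscle genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.554 with an estimated correlation), at a median of -0.12 (-0.03 and -0.43), and LMOD1, a leiomodin, went from 9.75 ± 1.30 to 2.28 ± 0.240 CPM (-1.71, by series -1.56 and -2.01). The contractile call, like the matrix call, was lost without control 1 (adjusted p = 0.23) or KD 3 (adjusted p = 0.234).

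Interferon response genes fell in pericytes as well, 14 of 37 with 1 that rose (16 and 1 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), at a median of -0.25 (-0.31 in the larger series and -0.29 in the other pair). IFIT2 fell from 15.5 ± 1.99 to 5.30 ± 0.274 CPM (-1.38, by series -1.32 and -1.501) and IFIT1 from 7.58 ± 1.26 to 2.63 ± 0.111 CPM (-1.23, by series -1.12 and -1.47). Of 29 p53 targets, 13 fell and 2 rose (14 and 2 adjusted over the list alone; adjusted p = 0.386 with an estimated correlation), at a median of -0.15 (-0.29 and -0.06). TP53INP1 fell by 0.78 (-0.84 and -0.65) and TIGAR by 0.70 (-0.69 and -0.72) on the log2 scale. Of 28 WNT signalling genes, 12 fell and 3 rose (13 and 3 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), at a median of -0.22 (-0.30 and -0.29). SFRP1 is on this list, and the receptor ROR1 went from 18.4 ± 3.23 to 5.08 ± 0.473 CPM (-1.66, by series -1.76 and -1.46).

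Regulators of lung mesenchyme fell in 10 of 30 with 3 that rose (13 and 3 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), at a median of -0.15 (-0.19 in the larger series and -0.13 in the other pair). HHIP, a hedgehog antagonist, fell from 19.96 ± 4.25 to 7.96 ± 1.01 CPM (-1.21, by series -1.02 and -1.60), and RARB, a retinoic acid receptor, from 8.79 ± 0.581 to 4.37 ± 0.200 CPM (-0.87, by series -0.84 and -0.91). Of 35 angiogenic signalling genes, 14 fell and 4 rose (15 and 4 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), at a median of -0.18 (-0.22 and -0.32). ANGPT1 fell from 37.5 ± 4.45 to 20.52 ± 2.31 CPM (-0.84, by series -0.99 and -0.54), while PDGFB went from 7.86 ± 4.83 to 16.0 ± 0.471 CPM (1.07, adjusted p = 0.0232; 1.49 and 0.23). The PDGFB call was lost without control 2 (adjusted p = 0.0939), control 3 (0.0668), KD 1 (0.0841) or KD 2 (0.0784), and without the code term (0.0729). Of 13 genes tied to pulmonary hypertension, 6 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation), at a median of -0.09 (-0.14 and -0.34). CAV1, a caveolin gene, fell from 624 ± 196 to 282 ± 7.69 CPM (-1.09, by series -1.36 and -0.54), and the BMP effector SMAD9 from 20.3 ± 0.837 to 13.5 ± 1.34 CPM (-0.56, by series -0.49 and -0.70). The lung mesenchyme call was lost without control 1 (adjusted p = 0.0563) or KD 3 (adjusted p = 0.0642). The angiogenic call was lost without genes that hold CCAGTA (adjusted p = 0.0533). That word was picked in these data for marking falls, so leaving out its genes takes fallen members out of a list that holds them.

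Of the remaining lists that fell, 34 adhesion and migration genes had 11 lower and 4 higher (14 and 4 adjusted over the list alone; adjusted p = 0.386 with an estimated correlation), at a median of -0.20 (-0.10 in the larger series and -0.22 in the other pair), and ALCAM fell by 0.94 on the log2 scale (-0.90 and -1.02). Of 24 YAP and TEAD targets, 9 fell and 3 rose (11 and 3 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation), at a median of -0.19 (-0.13 and -0.20), with MYOF at -0.49 (-0.62 and -0.24); 7 of the 9 held CCAGTA, and without genes that hold it the median was -0.01 and the call was lost (adjusted p = 0.517). Of 15 NOTCH genes, 7 fell and 2 rose (7 and 2 adjusted over the list alone; adjusted p = 0.352 with an estimated correlation), at a median of -0.13 (-0.16 and -0.07), with NOTCH2 at -0.64 (-0.68 and -0.55). The NOTCH call was lost as well without genes that hold CCAGTA (adjusted p = 0.0533). Of 37 ATF4 targets, 12 fell and 6 rose (13 and 6 adjusted over the list alone; adjusted p = 0.621 with an estimated correlation), at a median of -0.02 (-0.04 and -0.15). EPRS1, a tRNA synthetase, fell by 0.80 (-0.82 and -0.74) and MTHFD2 by 0.73 (-0.82 and -0.56); 7 of the 12 held CCAGTA, and without such genes the list median was 0.06 and the call was lost (adjusted p = 0.517). Without control 1 these 4 calls were lost (adjusted p = 0.0642, 0.0563, 0.0619 and 0.364 in that order), as they were without KD 3 (adjusted p = 0.0642, 0.0613, 0.0642 and 0.361). The YAP and NOTCH calls were lost without the code term too (adjusted p = 0.0788 and 0.0905). CCAGTA was picked in these data for marking falls, so leaving out its genes takes fallen members out of a list that holds them. Calls lost without its genes therefore do not tie the falls of the YAP, NOTCH and ATF4 lists to the word. Of 74 ribosomal protein genes, 13 fell and 3 rose (8 and 1 adjusted over the list alone; adjusted p = 0.782 with an estimated correlation), at a median of -0.07 that differed in sign between the series (-0.12 and 0.04). RPL23 changed by -0.45 (-0.53 and -0.28), and that list was not called without control 3 (adjusted p = 0.0606).

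Fibroblast markers in pericytes (9 fell and 3 rose of 20, as when adjusted over the list alone; median -0.15, adjusted p = 0.0974) were not called. Endothelial markers (1 rose and 1 fell of 11, as when adjusted over the list alone; adjusted p = 0.882) and epithelial markers (2 fell of 6, as when adjusted over the list alone; adjusted p = 0.414) were not called either. Of 5 immune markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.729), and mesothelial markers had under 5 tested members.

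Words of 3' UTRs went with falls in each cell type. Among genes searched in FLF, 23.3% of those with no copy of TCAGGT were called lower, against 31.0% with 1 copy and 39.5% with 2 or more. For CCAGTA in pericytes the shares were 12.5%, 23.7% and 33.8%. Of the 100 strongest falls, 74 held TCAGGT in FLF and 50 held CCAGTA in pericytes, against 34.8% and 28.0% of all genes searched. Both words were found in the same data that they describe. These shares are plain counts, without the adjustment for UTR length, GC content and expression that the z had. Longer 3' UTRs can hold more copies, so the rise with copies mixes the word with length. With those terms regressed out, holding the word had a z of -21.1 for TCAGGT in FLF and -15.3 for CCAGTA in pericytes. That z is of holding the word and not of the number of copies, and each word was picked for having the lowest z.

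**Figure D3:**
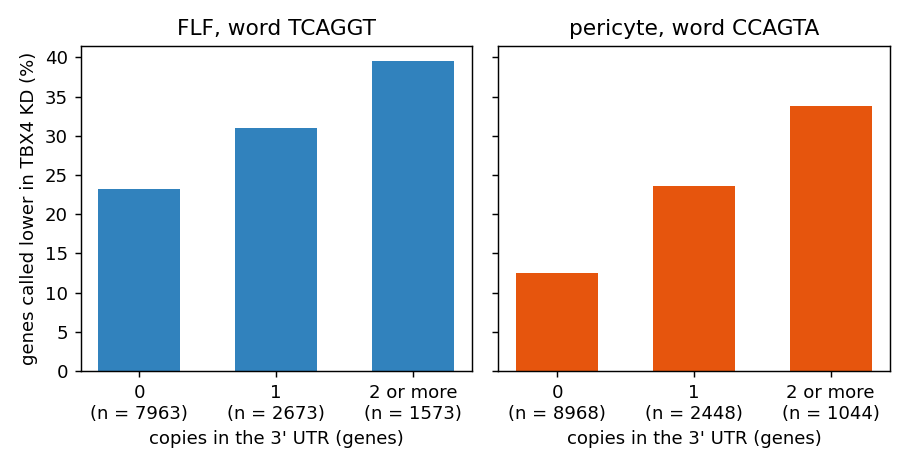
Percent of searched genes called lower in TBX4 KD (vertical axis) by number of copies of a 6-base word in the 3' UTR, for TCAGGT in FLF and CCAGTA in pericytes; n under each bar is the number of genes. The shares were 23.3, 31.0 and 39.5% in FLF and 12.5, 23.7 and 33.8% in pericytes, not adjusted for 3' UTR length.

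The series title names unique and overlapping genes, and the calls of both cell types were compared over 13209 genes tested in both. Shared falls numbered 630 against 514 from independent lists (odds ratio 1.41, Fisher exact p = 2.31e-10), and shared rises 461 against 476 (0.95, interval 0.85 to 1.07, Fisher exact p = 0.396). Genes that rose in FLF and fell in pericytes numbered 502 against 395 (1.45, Fisher exact p = 2.1e-10). Those that fell in FLF and rose in pericytes numbered 603 against 620 (0.96, Fisher exact p = 0.395). Pericyte falls were thus in excess among FLF calls of both directions, so the excess of shared falls was not particular to a common direction. Without genes that hold TCAGGT or CCAGTA, shared falls had an odds ratio of 1.86 (Fisher exact p = 1.46e-13). Shared rises then had 1.10 (Fisher exact p = 0.19). Opposite calls are not given for that run, so whether the same holds there is open. Over all genes the changes had a Spearman rho of 0.014, across genes, which are not independent replicates here or in the Fisher tests. The lower number of shared rises passed a threshold of 0.05 only without pericyte control 1 (0.90, Fisher exact p = 0.0309) or pericyte KD 3 (0.90, Fisher exact p = 0.0308).

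Besides TBX4, genes that fell in both cell types included KCNK6, a potassium channel gene (-1.29 in FLF and -1.04 in pericytes; -0.84 in the larger series and -1.43 in the other pair). PPP1R14A, an inhibitor of myosin phosphatase, fell by 0.99 and 1.29 (-0.92 and -2.02). LZTS1 fell by 0.72 and 1.39 (-1.64 and -0.88). The interferon-induced IFI6 fell by 0.92 and 1.31 (-0.87 and -2.19), its pericyte call being lost without KD 1 (adjusted p = 0.0532) or the code term (0.0957). KRT19, a keratin, fell by 0.43 in FLF and 1.93 in pericytes (-2.72 and -0.36), the pericyte call being lost without control 2 (adjusted p = 0.128), control 3 (0.0984), KD 1 (0.147) or KD 2 (0.126). SFRP1 fell by 0.21 in FLF, and MMP3 rose in FLF from 7.35 ± 0.347 to 20.9 ± 0.0875 CPM (1.39). Opposite calls included PLSCR4, a scramblase gene (1.19 in FLF and -1.53 in pericytes; -1.30 and -2.01). RGS4 rose by 0.40 in FLF, and OXTR, the oxytocin receptor, changed by 0.24 in FLF (adjusted p = 0.0419) and -2.22 in pericytes (-2.25 and -2.16). The FLF call of OXTR was lost without control 1, control 2 or KD 1.

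The KD effect itself differed between cell types for 5185 of 15103 genes, with 2981 higher and 2204 lower in pericytes than in FLF. Scaled by median of ratios, 2451 were higher and 2564 lower, so this balance depends on scaling. Among named genes tested in both cell types, CYP1B1, a xenobiotic-metabolizing enzyme, had the largest positive difference (2.32). IL1B (0.207 and 0.230 CPM in FLF control and KD) and HEPHL1 (0.0399 and 0.0252 CPM) were too low in FLF to be tested there, so their differences of 2.99 and 2.92 restate the pericyte change. CYP1B1 fell in FLF from 43.3 ± 0.561 to 9.90 ± 1.46 CPM (-2.03), with a pericyte change of 0.29 (adjusted p = 0.111; 0.49 and -0.12). PREX1, a Rac exchange factor, fell by 1.26 in FLF and rose by 0.69 in pericytes (0.73 and 0.61), a difference of 1.95. RGS4 (-3.04) and DDAH1 (-2.21) had the opposite sign, as did SLIT2, a guidance ligand, which rose by 0.90 in FLF and fell by 1.28 in pericytes (-1.54 and -0.76; difference -2.19). HMOX1 differed by -1.88. The count was 7192 without pericyte control 1 and 7174 without pericyte KD 3. It fell without the code term, to 1493 higher and 1234 lower. Falls went with a different 3' UTR word in each cell type. These differences may therefore be of the knockdown reagent rather than of cell type, which was not tested.

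Control pericytes and control FLF were compared as background. The inflammatory list was higher in pericytes and the fibrillar matrix list lower, with the preset correlation only (adjusted p = 0.29 and 0.427 with an estimated correlation). Of 14651 genes, 8741 differed, with 5200 higher and 3541 lower in pericytes; the count was 4962 and 5121 without FLF control 1 and 2. Median-of-ratios scaling gave 4488 higher and 4110 lower, so the size of the excess of higher calls depends on scaling. CXCL5, a neutrophil chemokine, was at 1145 ± 159 CPM in pericytes and 1.26 ± 0.134 CPM in FLF (8.97). CES1, a carboxylesterase, stood at 541 ± 216 against 0.856 ± 0.135 CPM (8.12), and SAA1 was higher by 8.06 on the log2 scale. IGFBP5 was at 32.6 ± 2.22 against 1588 ± 27.7 CPM (-5.57), CXCL12 at 12.01 ± 5.50 against 266 ± 12.05 CPM (-4.44), and SFRP1 lower in pericytes as well (-4.27). Of 18 pericyte markers, 3 were higher and 7 lower in the pericyte libraries (3 and 6 adjusted over the list alone; median -0.40, adjusted p = 0.0359, and adjusted p = 0.427 with an estimated correlation). CSPG4 (-1.58) and PDGFRB (-2.20) were among the lower ones. Of 24 fibroblast markers, 5 were higher and 14 lower (5 and 14 adjusted over the list alone; median -0.71, mean 0.03, adjusted p = 0.0286, and adjusted p = 0.427 with an estimated correlation). Of 36 fibrillar matrix genes, 22 were lower and 3 higher (24 and 3 adjusted over the list alone; median -1.13, adjusted p = 0.427 with an estimated correlation), and of 33 inflammatory genes, 26 were higher and 1 lower (26 and 1 adjusted over the list alone; median 1.64, adjusted p = 0.29 with an estimated correlation).

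Other marker lists between the controls were contractile genes (3 higher and 13 lower of 26, as when adjusted over the list alone; adjusted p = 0.00424, and adjusted p = 0.601 with an estimated correlation) and epithelial markers (1 higher and 3 lower of 6, as when adjusted over the list alone; adjusted p = 0.337). Endothelial (5 higher and 2 lower of 10, as when adjusted over the list alone; adjusted p = 0.793), immune (3 higher of 5, or 4 adjusted over the list alone; adjusted p = 0.1) and mesothelial markers (3 higher and 1 lower of 5, as when adjusted over the list alone; adjusted p = 0.564) were not called. Cell type could not be told apart from library numbering in this comparison.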

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

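The 3' UTR word searches and the count over other splits of the pericyte libraries were set out before their results were seen, and the comparison of the library-code series was chosen afterwards. Values in the next 4 paragraphs are differences of the KD effect (pericytes minus FLF, log2 scale) that passed an adjusted p of 0.05 in the interaction term of limma, which is why they are listed. Of 15103 genes, 5185 did. IL1B, HEPHL1, CCL20, IL1A, CSF3, SAA2, CADM3, RARB, PDGFB, CES1 and SAA1 were too low in FLF to be tested there, and COL11A1 and LDB3 too low in pericytes. On the log2(CPM + 1) scale the difference for these 13 genes largely restates the change in 1 cell type. Cell type could not be told apart from library numbering, and TBX4 was left at 46.6% of control in FLF and 19.7% in pericytes. Falls also went with a different 3' UTR word in each cell type, and the knockdown method is not stated. A difference between the knockdown reagents therefore could not be told apart from a difference between the cell types.

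TBX4 itself differed by -0.75. Of genes that rose in FLF, HMOX1 differed by -1.88, ASNS by -1.68, PSAT1 by -1.69, CHAC1 by -1.32, TRIB3 by -1.28, ALDH1L2 by -1.65, MET by -1.31, MTHFD2 by -1.86, SESN2 by -1.08, EPRS1 by -1.39, GCLM by -0.74, SRXN1 by -0.46, SPARC by -0.95 and COL11A1 by -1.18. MT-ND4 differed by -0.60 and MT-ND3 by -0.74. LDB3 differed by -2.68, but it is one of the heart muscle transcripts that were unequal between the FLF knockdown libraries (9.71 and 4.40 CPM), and its FLF call was lost without control 1 (adjusted p = 0.186) or control 2 (adjusted p = 0.19). Of genes that fell in FLF, CPA4 differed by 1.67, SLC2A4RG by 1.07, MYBL2 by 1.17, TRAK2 by 0.79, IRAK1 by 1.23, TNFAIP2 by 1.4995, IGF2BP3 by 1.24, CYP1B1 by 2.32 and PREX1 by 1.95. KIF4A differed by 0.62, UBE2C by 0.43, RRM2 by 0.89, MCM5 by 0.73, EPSTI1 by 0.94, ISG15 by 0.56, HLA-B by 0.73, PSMB9 by 0.78, P4HA2 by 0.99, SLC2A1 by 1.04, NDUFA2 by 0.73, ZMAT3 by 0.42 and RRM2B by 0.35.

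Of genes that rose in pericytes, IL1B differed by 2.99, HEPHL1 by 2.92, CCL20 by 2.25, IL1A by 1.88, CSF3 by 2.08, SAA2 by 1.76, IER3 by 1.44, PDGFB by 1.18, CXCL5 by 1.12, CES1 by 1.65, SAA1 by 1.69 and IGFBP5 by 0.74. The IL1B difference lost its call when any FLF library was left out, and with voom on estimated reads (adjusted p = 0.752).

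Of genes that fell in pericytes, RGS4 differed by -3.04, CADM3 by -2.14, DDAH1 by -2.21, CAPNS1 by -1.67, ITGBL1 by -1.86, ADAMTSL1 by -1.83, PRUNE2 by -1.63, SLIT2 by -2.19, LZTS1 by -0.67, PLSCR4 by -2.73 and OXTR by -2.45. IFIT2 differed by -1.33, IFIT1 by -0.90, TIGAR by -0.98, CSPG4 by -1.11, PDGFRB by -0.49, COL1A2 by -1.74, COL3A1 by -1.70, LOX by -1.33, ROR1 by -1.57 and RPL23 by -0.60. HHIP differed by -0.76, RARB by -0.94, LMOD1 by -1.69, ANGPT1 by -1.33, CAV1 by -1.67, SMAD9 by -0.39, ALCAM by -1.05, MYOF by -0.44 and NOTCH2 by -0.64.

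Among lists, the median difference was -0.69 for ATF4 targets, -0.50 for fibrillar matrix, -0.49 for mitochondrially encoded transcripts, -0.46 for pericyte markers, -0.37 for angiogenic signalling, -0.34 for lung mesenchyme regulators, -0.21 for contractile genes and -0.11 for adhesion genes. It was 1.15 for inflammatory NF-kB genes, 0.82 for the senescence-associated secretory program, 0.51 for HLA class I, 0.33 for immediate early genes, 0.29 for mitosis, 0.29 for DNA replication, 0.29 for hypoxia and glycolysis and 0.23 for nuclear oxidative phosphorylation genes. These 16 lists passed with the preset correlation, and none passed with an estimated one (smallest adjusted p = 0.0787).

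Falls in each cell type went with a word of the 3' UTR, and with a different word in each. In FLF the most negative z of any 7-base word was -18.44 (TCAGGTA), against -5.06 as the lowest in 100 shufflings, and in pericytes it was -18.72 (TCCAGTA), against -5.12. The same words had a z of 0.49 and 1.72 in the other cell type, and 5 of the 10 lowest words in each were shifted by a base from the lowest one. These values are consistent with off-target silencing through the seed of a small RNA that differed between the cell types, as a hypothesis, since the labels state no knockdown method. A change of an endogenous small RNA was not tested and stays open. Without genes holding the core words 3850 genes were called in FLF and 3245 in pericytes, against 6145 and 4732 with all genes. That setting takes 34.8% of searched genes in FLF and 28.0% in pericytes out of testing, called or not. The drop in calls is therefore no measure of off-targets.

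The pericyte changes differed in size between the library-code series. All libraries of the larger series carry the same code, so a code difference has no part in its 7664 calls. Of these genes 76.9% had the same sign in the pair of the smaller series, as did 91.4% of the 280 with at least 2-fold change, and the changes of the 2 series had a Spearman rho of 0.485 across genes. What set the series apart was not tested. Calls of the larger series rest on the spread within its groups (chi-square per gene 2.35 and 3.04). That spread was smaller than the one across series (19.9 to 70.8). A count over the 10 splits of the 6 libraries into 3 and 3 gave 1 split with as many calls, the real one with 4732, and the highest other split gave 0. With 10 splits no share under 0.05 can be reached.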

How the results depend on the processing

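Scaling by median of ratios, voom on estimated reads, scaling without mitochondrial genes and leaving out genes with the core word were chosen after seeing the data. TBX4 kept its direction and call under every alternative run. Of 5251 alternative values for 337 named gene results, 4901 stayed on their side of the threshold, 350 lost the call and 0 changed direction; for 28 list results, 427 of 459 stayed, 31 lost the call and 1 changed sign. That was the ATF4 list in pericytes without core-word genes (median 0.064, adjusted p = 0.517). By construction fewer genes remained with at least 2-fold change (113 in FLF, 221 in pericytes) and without core-word genes (3850 in FLF). Camera with an estimated correlation called 0 lists in FLF and 0 in pericytes, against 11 and 17 with the preset one. That setting is not among the 459 list values above, so their tally leaves out the setting in which every list call was lost. Leaving out 1 library at a time gave 4592 to 5360 calls in FLF, 2342 to 7670 in pericytes, 3562 to 7192 for the interaction and 4962 to 11531 between controls, with the lone library assumed to vary like the other groups; odds ratios of shared rises ran from 0.896 to 0.976. In pericytes the larger code series alone gave 7664 calls and no code term 1825; the interaction gave 2727 without it. Without a filter the odds ratio of shared rises turned to 1.56 (Fisher exact p = 1.23e-11), and that of shared falls rose from 1.41 to 2.50; the background then held unexpressed genes. The cause of the other changes was not tested. Median-of-ratios scaling gave 1972 higher and 2381 lower pericyte calls and 3027 and 3095 in FLF. Depth limits calls near 0.0548 to 0.0810 CPM.

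Whether replicate numbers pair the samples stayed open. Same-number deviations correlated at -0.29, 0.26 and -0.30 in pericytes, where not every library correlated best with its own number. Numbers 1 and 3 there join libraries of different code series, so these values cannot tell pairing from the code difference. In FLF the correlation was 0.07 for the same number and -0.07 for the other. With 2 libraries per group these are equal and opposite by construction. With the number as a block the calls were 6846 in FLF, 541 in pericytes and 1404 for the interaction (692 higher and 712 lower).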

Other observations

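The tests of this part, on heart muscle and mitochondrial transcripts, were chosen only after the result was seen.

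Heart muscle transcripts appeared in the FLF knockdown libraries. Of 68 listed genes, 58 were above both controls in both KD libraries, and 37 were high enough to be tested. Of these 25 rose and 1 fell, and the 23 that rose by at least 1 CPM were kept for the ratios. Besides MYH7, MYL7, an atrial light chain, was listed at the offset in both controls and at 27.0 and 10.8 CPM in KD 1 and 2, and TNNT2, cardiac troponin T, was at 26.4 and 10.7 CPM. MYH6 stood at 0.111 and 0.0470 CPM in controls and 23.6 and 9.98 CPM in KD, and the atrial peptide gene NPPA at 10.5 and 4.92 CPM in KD. NKX2-5, a cardiac transcription factor, was at 2.11 and 1.16 CPM in KD. These 23 genes, chosen because they rose, summed to 22.8 and 25.9 CPM in FLF controls and 289 and 141 CPM in KD. The other 45 summed to 209.9 and 198 CPM in controls and 293 and 213 CPM in KD.

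The excess of these transcripts over controls was 2.2681 times as large in KD 1 as in KD 2 at the median of the 23 genes chosen for having risen (quartiles 2.15 and 2.40). Over 2531 other genes chosen the same way, the quartiles were 0.843 and 1.25 and the 95th percentile 1.9175, which argues against a response of equal size in both libraries. One outside source of heart muscle RNA or reads, in unequal amounts, may account for the ratio, and a fibroblast response that differed between the 2 libraries was not tested. The ratio for mitochondrially encoded transcripts was 2.1187, inside the range of the cardiac genes (1.09 to 2.88) and just below their lower quartile, so whether they share that source cannot be told apart from a rise of their own.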
